A study of Mus musculus with 6 samples.

How the data were processed

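The data are 6 microarrays of total RNA from Treg cells, 3 from pancreas and 3 from spleen, of 10-week-old female NOD mice with a Foxp3 reporter. Per the labels, cells were sorted as DAPI-negative CD4+ TCRb+ CD45+ GFP+ cells, collected in TRIzol after a second sort, and their RNA was amplified with the Ambion WT Expression Kit and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. Amplification of RNA from few sorted cells can change the measured width of the intensity distribution between arrays. The deposited values are linear probe-set intensity values made with RMA and Affymetrix Power Tools, per the submitters' processing notes, with no versions given. RMA corrects background, quantile-normalises and summarises probes. The deposited columns did not share 1 distribution, since their medians ranged from 82.0 to 92.0, so how arrays were normalised together is not given in the sources used here. The values ran from 4.78 to 17604 and were taken to log2 with no pseudocount, filter or further normalization.

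The table held 24922 probe sets. In the platform annotation 21425 of them name exactly 1 gene, 1399 several and 2098 none, and only the first were used for genes. Of these, 21347 matched the RefSeq gene table of GRCm38.p6 by gene ID, which updated 0 symbols. For 921 genes with several probe sets, the probe set with the highest mean over all 6 arrays was used, which left 19752 genes. No coordinates were used, since the genome build of the annotation is not given in the sources used here. The background level was the 95th percentile, over 1194 olfactory and vomeronasal receptor genes, of the mean log2 value, which was an intensity of 63.9, and 11698 genes had a mean above it. Where all arrays of the lower tissue were below background, the fold is a lower bound, with the higher tissue's mean set against the background level. Where only some were and the lower tissue's mean was below background, those arrays were raised to that level, a choice made after seeing the data. Genes were ranked by the fitted log2 fold change, which for such genes is not exact.

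The groups came from the tissue in the labels. Genes were compared with limma (version 3.58.1 in R 4.3.3), fitting lmFit and eBayes to all 6 arrays with no covariates, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are pancreas against spleen. The prior had 6.58 degrees of freedom beside 4 residual ones. Gene lists were compared with limma's camera, with a preset inter-gene correlation of 0.01 and adjustment over the 34 lists, and again with an estimated correlation and with fry. The 34 lists held 546 different genes, of which 486 were measured. They covered Treg, helper, activation, trafficking and metabolic programmes, markers of other cells, and sorting markers. They, the tests, the background level, the alternatives and the rule for naming genes were fixed before the data were examined. List members without a probe set of their own are not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

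The rule named the 12 genes in each direction with the largest log2 fold change. These had to be past the threshold, with the arrays of the tissues not overlapping, above background in the higher tissue and on no list of other cells. Predicted or clone names, receptor and immunoglobulin variable segments and olfactory receptors were left out. Of 79 such genes higher in pancreas and 24 higher in spleen, the first 12 of each are given. It also named up to 4 members above background with the smallest adjusted p of each programme list, up to 3 members above background with the largest change of each list of other cells, and always Foxp3, Il2ra, Ctla4, Ikzf2, Cd4, Ptprc, Tbx21 and Cxcr3. Genes named outside this rule are said to be so.

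The fit was tested on simulated data with each gene's fitted residual spread, in 5 runs with 200 changed genes each. It called 5.20% of genes changed by 0.5 on the log2 scale, 82.4% of those changed by 1, and 100% of those changed by 2 or 4, and 5.27% of its calls were false. A list shifted by 0.5 was found in 5 of 5 runs, with 1 false call in 160 tests of unshifted lists. The simulated genes were independent, so these rates do not cover correlated genes. Nor do they cover arrays of different width, since the simulated arrays shared 1 width. The interquartile range of the real arrays ran from 2.23 to 3.07 on the log2 scale. Alternatives covered normalization, background, dim genes, several probe sets per gene, the variance model, array weights, members shared between lists, marker genes of other cells, the replicate number as a block, and each array left out. Those on the spread of the arrays, and the 2-fold count without marker genes of other cells, were chosen after seeing the data.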

Results

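Gene expression was measured in regulatory T (Treg) cells, the CD4 T cells that express the transcription factor Foxp3 and restrain immune responses, from 2 tissues of female NOD mice. NOD mice develop autoimmune diabetes spontaneously, and these animals were 10 weeks old and prediabetic. They carried a reporter that couples green fluorescent protein to Foxp3, so that Treg cells could be sorted as viable CD45+ TCRb+ CD4+ GFP+ cells. There were 3 arrays of pancreatic and 3 of splenic Treg cells, hybridised to Affymetrix Mouse Gene 1.0 ST arrays. The comparison asks how Treg cells in the tissue under autoimmune attack differ from those of a lymphoid organ. The median intensity of the 6 arrays lay between 82.0 and 92.0, and 11123 to 12409 of the 19752 genes tested per array were above the background level, an intensity of 63.9. For arrays, the number of arrays limits the precision of each value. The labels do not say whether the arrays came from separate mice or pools, so p-values measure only the spread between these samples, which may be technical.

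The arrays resembled each other closely, with Pearson correlations across genes of 0.966 to 0.992 within a tissue and 0.961 to 0.987 between tissues (genes are not independent replicates). The first principal component held 50.3% of the variance and did not separate the tissues. The second held 27.5% and did, with all 3 pancreas arrays below 0 and all 3 spleen arrays above. The width of the log2 distribution differed within each tissue, with an interquartile range of 3.07, 2.72 and 2.23 on pancreas arrays 1 to 3 and of 2.49, 2.80 and 3.00 on spleen arrays 1 to 3. The first component ran with this width. It was at -0.44 on spleen array 3 and -0.40 on pancreas array 1, both wide, and at 0.21 on spleen array 1 and 0.76 on pancreas array 3, both narrow.

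Pancreatic Treg cells had a higher level of Il10, the gene of an anti-inflammatory cytokine, than splenic ones, with a log2 intensity of 9.07 ± 0.17 against 5.62 ± 0.45 (SD, n = 3 each). All 3 spleen arrays were below background for Il10, so the difference was at least 8.41-fold (adjusted p = 7.72e-05). The chemokine gene Ccl3, with 1 of 3 spleen arrays above background, was at least 6.77-fold higher in pancreas (adjusted p = 7.70e-05), and the chemokine receptor gene Cxcr6 was 4.66-fold higher (2.22 ± 0.17 SE, adjusted p = 0.000303). In the other direction, Tlr7, an endosomal RNA sensor, was lower in pancreas, at 6.78 ± 0.26 against 8.14 ± 0.04 (log2 fold change -1.36, adjusted p = 0.00693), as was Gpr83, a G protein-coupled receptor abundant in Treg cells (-1.26, adjusted p = 0.0125). Across the 19752 genes, 134 differed between tissues at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 108 higher in pancreas and 26 higher in spleen. Of these, 119 were at least 2-fold apart, 99 higher in pancreas and 20 in spleen. Of the 134 genes, 28 stood on the lists of markers of other cells, all 28 higher in pancreas. With the genes of those lists left out, and the fit and adjustment redone over 19618 genes, 77 genes passed, all among the 134. The calls that ended therefore include genes on no such list, whose values were the same. The 3 arrays of each tissue did not overlap for 2049 of the 19752 genes, near the 10% of genes that chance alone gives. Of the 2049, 902 were higher in pancreas and 1147 in spleen. The count of 134 fell to 38 with each array centred on its median and to 3 with values under background set to that level. The latter setting left 6588 genes with no spread and took the prior degrees of freedom from 6.58 to 0.353. Of the 134 genes, 89 had every value above background, so their values and folds stayed the same, and 0 of the 89 passed. The drop to 3 therefore does not show that their differences depend on background. With 1 array left out, the count ranged from 64 without spleen array 1 to 262 without pancreas array 3.

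The genes with the largest differences outside the marker lists of other cells were named by a fixed rule, 12 in each direction. Higher in pancreas were Il10, Ccl3 and Pla2g1b (log2 fold change 3.08), which encodes the secreted phospholipase of pancreatic juice. Lilr4b, with all 3 spleen arrays below background, was at least 4.02-fold higher, and its near-identical neighbour in the same receptor family, Lilrb4a, had a log2 fold change of 2.25, and their probe sets may share signal. Scd1, a fatty acid desaturase, was at least 3.57-fold higher, with 1 of 3 spleen arrays above background. Dmbt1, a secreted glycoprotein of epithelia, was at least 3.08-fold higher. The remaining genes were Cxcr6, the chemokine gene Ccl5 (2.08), the AP-1 transcription factor gene Fos (2.06), the granzyme gene Gzmk (1.95) and the co-inhibitory receptor gene Lag3 (1.94). Pla2g1b and Dmbt1 stood beside a higher level of acinar genes on the same arrays, with a median log2 fold change of 3.05 over the acinar list. Of these 12, the calls of Scd1 and Ccl5 ended in 3 of the 6 fits with 1 array left out (adjusted p up to 0.108 and 0.0643), and that of Lag3 without pancreas array 1 (adjusted p = 0.0594).

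With all 6 arrays, fewer of the genes past the test were higher in spleen, 26 against 108. At an unadjusted limma p under 0.05 the balance turned, with 719 genes higher in spleen and 632 in pancreas. The balance of 26 against 108 did not hold without pancreas array 1, where 44 genes were higher in spleen and 46 in pancreas. In the other 5 fits with 1 array left out more genes were higher in pancreas, and over all 6 of these fits the number higher in spleen ran from 4 to 44. The largest differences were Qser1 (log2 fold change -1.77), Cybrd1, a ferric reductase gene (-1.59), Amigo2, an adhesion molecule gene (-1.58), Arhgap20 (-1.48) and Tlr7. They were followed by Ift80 (-1.28), the sodium pump subunit gene Atp1b1 (-1.28), Gpr83, Treml2 (-1.15), the kinase gene Sgk3 (-1.14), the survival gene Bcl2 (-1.14) and Zfp617 (-1.10). Of these 12, Qser1, Amigo2 and Tlr7 passed the test in each of the 6 fits with 1 array left out, but the call of Qser1 ended with each array centred on its median (adjusted p = 0.0653). The calls of the other 9 ended without pancreas array 2 or spleen arrays 1, 2 or 3 in some of these fits, with Bcl2 and Zfp617 reaching an adjusted p of 0.224 and Ift80 of 0.217.

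**Figure D1:**
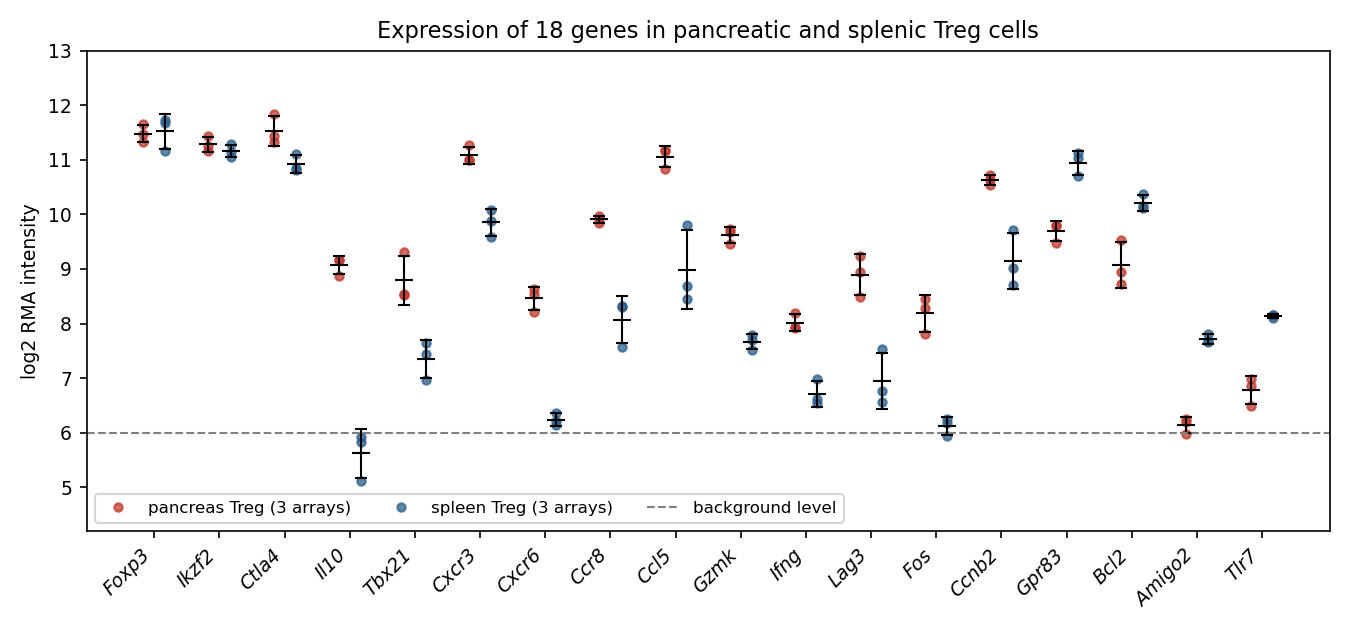
Log2 RMA intensity (vertical axis) of 18 genes (horizontal axis) on each array, with pancreatic Treg cells in red and splenic Treg cells in blue. Points are the 3 arrays of each tissue, horizontal marks the mean and error bars 1 SD, and the dashed line is the background level (intensity 63.9, drawn on the log2 scale); all 3 pancreas points of Il10 lie above it and all 3 spleen points below it, while the points of Foxp3 overlap between tissues.

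The genes that define the sorted population were at similar levels. Foxp3 was at 11.48 ± 0.16 in pancreas and 11.52 ± 0.32 in spleen (log2 fold change -0.04 ± 0.20 SE, not past the test), and Ikzf2, which encodes the Treg transcription factor Helios, at 11.29 ± 0.13 and 11.16 ± 0.12. Cd4 had a log2 fold change of -0.09 and Ptprc, the gene of CD45, of -0.21, neither past the test. Of the 10 measured sorting and T cell identity genes, 0 passed the test in either direction, and the list did not shift (median log2 fold change -0.05, camera adjusted p = 0.872). In the Treg core signature, 1 of 18 genes was higher in pancreas and 1 lower, and 3 were higher and 1 lower when adjusted over the list alone. Those past the test over all genes were Tigit, a co-inhibitory receptor gene (log2 fold change 0.88, adjusted p = 0.0473), and Gpr83. The call of Tigit ended with the replicate number as a block (adjusted p = 0.162). Ctla4 (0.60 ± 0.19 SE, adjusted p = 0.318) and Il2ra, the gene of the high-affinity IL-2 receptor chain (-0.32, adjusted p = 0.842), did not pass, nor did the list in camera (adjusted p = 0.145). The core list did pass mixed fry, which counts members that move in either direction (adjusted p = 3.14e-05). Its members therefore differed between tissues without a common direction.

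Genes of tissue-resident and effector Treg cells were higher in pancreas, on a list whose members Il1rl1 and Areg had no probe set of their own. Of 22 measured, 20 had a higher mean in pancreas, 5 passed the test over all genes and 11 when adjusted over the list alone. They included Il10, the chemokine receptor gene Ccr8 (9.91 ± 0.07 against 8.07 ± 0.43, 3.59-fold), the transcriptional repressor gene Prdm1 (log2 fold change 1.21, adjusted p = 0.0215) and Fgl2, which encodes a secreted suppressive protein (1.33, adjusted p = 0.0245). The list shifted by a median of 0.69 (camera adjusted p = 3.66e-24), with adjusted p = 0.0984 with an estimated correlation. The suppressive mediators, which share Il10 and Fgl2 with this list, shifted by a median of 0.53 (adjusted p = 7.86e-12, and adjusted p = 0.140 with an estimated correlation). There, 3 of 16 genes rose over all genes, the third being Lag3, and 9 rose adjusted over the list alone. This call ended when members standing on other programme lists were left out. Among the co-inhibitory receptors, Lag3 and Tigit rose, 2 of 12, with 4 higher and 2 lower adjusted over the list alone. Havcr2, the gene of TIM-3, was at 1.05 (adjusted p = 0.0667), and Cd96 was at -0.62 (adjusted p = 0.195). That list passed (adjusted p = 0.0245, and adjusted p = 0.386 with an estimated correlation), but not without pancreas array 1 or spleen array 1 (adjusted p up to 0.378), and without members standing on other lists its median turned to -0.16. On the same arrays the acinar markers had a median log2 fold change of 3.05, the B cell markers of 0.78 and the macrophage and dendritic cell markers of 0.29, and B cells and macrophages can also express Il10, Prdm1 and Fgl2. The calls of Prdm1 and Tigit held in 1 of the 6 fits with 1 array left out, and that of Fgl2 in 2.

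Genes of the T helper 1 (Th1) programme were higher in pancreas. Of 15 measured, 6 rose over all genes and 7 adjusted over the list alone. Tbx21, which encodes the Th1 master transcription factor T-bet, was 2.71-fold higher (8.79 ± 0.45 against 7.35 ± 0.35, adjusted p = 0.0324), its target Cxcr3, a chemokine receptor gene, 2.35-fold (adjusted p = 0.0148), and the interferon gamma gene Ifng 2.47-fold (adjusted p = 0.00952). Ccl5, Gzmk and the cytotoxic granule gene Nkg7 (log2 fold change 1.92, adjusted p = 0.00169) made up the 6. The list shifted by a median of 0.53 (camera adjusted p = 1.20e-17, and adjusted p = 0.0984 with an estimated correlation). Of the chemokine receptors, Cxcr6, Ccr8 and Cxcr3 rose, 3 of 17, with 4 higher and 1 lower adjusted over the list alone. That list had a median of 0.03 (adjusted p = 0.00893, and adjusted p = 0.358 with an estimated correlation), and its call ended without pancreas array 1 (adjusted p = 0.167), with array weights and in directional fry. Without pancreas array 2 its median turned to -0.0272. On the same arrays the CD8 T and NK cell markers had a median of 0.24, or -0.02 over their 5 members above background (adjusted p = 0.957), and the acinar (median 3.05), B cell (0.78) and macrophage and dendritic cell markers (0.29) rose. The calls of Gzmk, Nkg7 and Ifng held in all 6 fits with 1 array left out, whereas those of Ccl5 and Cxcr3 held in 3. That of Tbx21 held in 2, with an adjusted p of up to 0.105 over the 6 fits.

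The other helper programmes showed little. The Th17 list shifted by a median of 0.22 with 0 of 8 genes past the test over all genes and 2 adjusted over the list alone (adjusted p = 0.0154, and adjusted p = 0.158 with an estimated correlation). Its call ended without pancreas array 1 or spleen array 3 (adjusted p up to 0.0824), with array weights and in directional fry, and its member with the smallest p, the aryl hydrocarbon receptor gene Ahr, was at 0.78 (adjusted p = 0.180). The Th2 list (9 genes, adjusted p = 0.999) and the follicular T cell list (11 genes, adjusted p = 0.0640) did not pass, with 0 genes past the test in either. For Th2 the median (-0.07) and the mean (-0.01) were below 0 while the test pointed upward.

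Genes of naive and central T cells were lower in pancreas. All 16 measured members had a lower mean there, 2 fell over all genes and 13 adjusted over the list alone. The 2 were Bcl2 (9.07 ± 0.42 against 10.21 ± 0.14, adjusted p = 0.0482) and Dapl1 (log2 fold change -1.10, adjusted p = 0.0495). Both calls ended in 4 of the 6 fits with 1 array left out (adjusted p up to 0.224 and 0.218), that of Bcl2 also with the replicate number as a block (adjusted p = 0.0546) and that of Dapl1 with a trended and robust variance, and both with each array centred on its median. Bach2, which encodes a repressor of effector differentiation, was at -1.02 (adjusted p = 0.0951) and Igfbp4 at -0.92 (adjusted p = 0.0842). The list shifted by a median of -0.76 (camera adjusted p = 8.14e-21, and adjusted p = 0.0984 with an estimated correlation). It was the only list of the 34 that passed in this direction. On the same arrays the acinar (median 3.05), B cell (0.78) and macrophage and dendritic cell markers (0.29) rose. Dilution of Treg RNA by RNA of such cells would lower T cell genes in general. With 1 array left out, the median of the sorting and T cell identity list ran from -0.16 to 0.0425. That of the naive list ran from -0.84 to -0.67. These values argue against dilution as the whole cause for the naive genes as a set.

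Cell cycle genes were higher in pancreas. All 27 measured members had a higher mean there, 10 rose over all genes and 27 adjusted over the list alone, by a median log2 fold change of 1.14 with a range of 0.60 to 1.67. They included the ribonucleotide reductase gene Rrm2 (2.82-fold, adjusted p = 0.0157), the mitotic kinase gene Aurkb (2.65-fold, adjusted p = 0.0170), the spindle gene Tpx2 (higher by at least 1.32 on the log2 scale, with 1 of 3 spleen arrays above background, adjusted p = 0.0191) and the cyclin gene Ccnb2 (10.63 ± 0.09 against 9.14 ± 0.51, adjusted p = 0.0207). The list's shift passed camera (adjusted p = 1.03e-51, and adjusted p = 0.0984 with an estimated correlation). On the same arrays the B cell markers had a median log2 fold change of 0.78, the acinar markers of 3.05 and the macrophage and dendritic cell markers of 0.29. The calls of Rrm2 and Tpx2 ended in 2 of the 6 fits with 1 array left out and those of Aurkb and Ccnb2 in 4, with adjusted p up to 0.0870, while the list's call held in all 6.

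Immediate-early and stress genes were higher in pancreas. All 22 measured members had a higher mean there, 6 rose over all genes and 12 adjusted over the list alone. Fos was at 8.19 ± 0.34 against 6.13 ± 0.16, and its family member Fosb (log2 fold change 1.23, adjusted p = 0.00779) and Jun (1.94, adjusted p = 0.0207), whose protein pairs with both, rose with it, as did Rgs2, a regulator of G protein signalling (1.87, adjusted p = 0.00920). The list shifted by a median of 0.66 (camera adjusted p = 5.26e-21, and adjusted p = 0.0984 with an estimated correlation). The T cell receptor (TCR) activation genes had a median of 0.25 (adjusted p = 0.000128, and adjusted p = 0.419 with an estimated correlation), which ran from 0.0910 without spleen array 1 to 0.407 without spleen array 3. That call ended without pancreas array 1 or spleen array 1 (adjusted p up to 0.0964) and in directional fry. There 1 of 17 genes rose, the nuclear receptor gene Nr4a2 (3.60-fold, adjusted p = 0.00952), and 3 rose adjusted over the list alone. Its relative Nr4a1 was at 1.10 (adjusted p = 0.188). Of 13 NF-kB targets, 2 rose, over all genes and over the list alone, both feedback inhibitors of the pathway: Tnip3 (at least 1.97-fold, with 1 of 3 spleen arrays above background, adjusted p = 0.0207) and Tnfaip3 (log2 fold change 1.27, adjusted p = 0.0355). That list had a median of 0.29 (adjusted p = 7.52e-05, and adjusted p = 0.383 with an estimated correlation), and its call ended without spleen array 1 (adjusted p = 0.0681) and in directional fry. Over the fits with 1 array left out its median ran from 0.0470, without spleen array 1, to 0.560. The acinar (median 3.05), B cell (0.78) and macrophage and dendritic cell markers (0.29) rose on the same arrays, and those cells can also express Fos, Jun and Rgs2. The calls of Rgs2 and Nr4a2 ended without pancreas array 1 (adjusted p = 0.0540 and 0.0562), that of Jun without pancreas array 1 or 2, and those of Tnip3 and Tnfaip3 in 4 and 5 of the 6 fits with 1 array left out.

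Interferon genes differed little. Of 16 interferon gamma response genes, 1 rose over all genes, the transcription factor gene Irf8 (2.24-fold, adjusted p = 0.0183), and 3 adjusted over the list alone. The list had a median of 0.07 (adjusted p = 0.000612, and adjusted p = 0.353 with an estimated correlation). The call of Irf8 ended without pancreas array 2 or spleen array 1 (adjusted p up to 0.105), and that of the list without pancreas array 1 (median -0.0203, adjusted p = 0.177). Of 21 type I interferon response genes, 0 passed over all genes or over the list alone, and the list did not pass (median -0.08, adjusted p = 0.407). Irf8 is also expressed by B cells and dendritic cells. The B cell list and the joint macrophage and dendritic cell list were higher on the pancreas arrays. MHC class II genes of the joint list are also expressed by B cells, so it does not single out dendritic cells. On pancreas arrays 1 to 3 Irf8 was at 9.05, 9.31 and 9.08, and the B cell list had medians of 7.04, 6.31 and 7.36. With 3 arrays this cannot decide the source of Irf8.

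Of the metabolic lists, glycolysis had a median of 0.31 with 0 of 13 genes past the test over all genes and 1 over the list alone (adjusted p = 0.000104, and adjusted p = 0.383 with an estimated correlation), where Tpi1 was at 0.61 (adjusted p = 0.197). The call of glycolysis ended without pancreas array 1 or spleen array 1 (adjusted p up to 0.0615) and in both fry tests. Oxidative phosphorylation had a median of 0.09 with 0 of 23 genes past either test (adjusted p = 0.0414, and adjusted p = 0.671 with an estimated correlation), and its call ended in 4 of the 6 fits with 1 array left out (adjusted p up to 0.871), with the replicate number as a block, in both fry tests and with the mean of a gene's probe sets in place of the brightest. Cholesterol synthesis (15 genes, adjusted p = 0.269) and the cytosolic ribosomal proteins (18 genes, adjusted p = 0.305) did not pass. Integrins and adhesion genes had a median of 0.06, with 0 of 17 past the test over all genes and 4 higher and 1 lower over the list alone. The integrin gene Itgae, which encodes CD103, was at 0.83 (adjusted p = 0.131) and Alcam at 0.78 (adjusted p = 0.0644). That list passed (adjusted p = 0.00371, and adjusted p = 0.419 with an estimated correlation), but not without the members it shares with other lists, without pancreas array 1 or spleen array 1 (adjusted p up to 0.378), with array weights or in directional fry. Without spleen array 1 its median turned to -0.0170. The co-stimulatory receptors (11 genes, adjusted p = 0.0640), the targets of IL-2 and STAT5 (15 genes, adjusted p = 0.681) and the TGF-beta response (12 genes, adjusted p = 0.130) did not pass. The calls of glycolysis, oxidative phosphorylation and integrins stand beside the higher acinar (median 3.05), B cell (0.78) and macrophage and dendritic cell markers (0.29) of the same arrays.

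**Figure D2:**
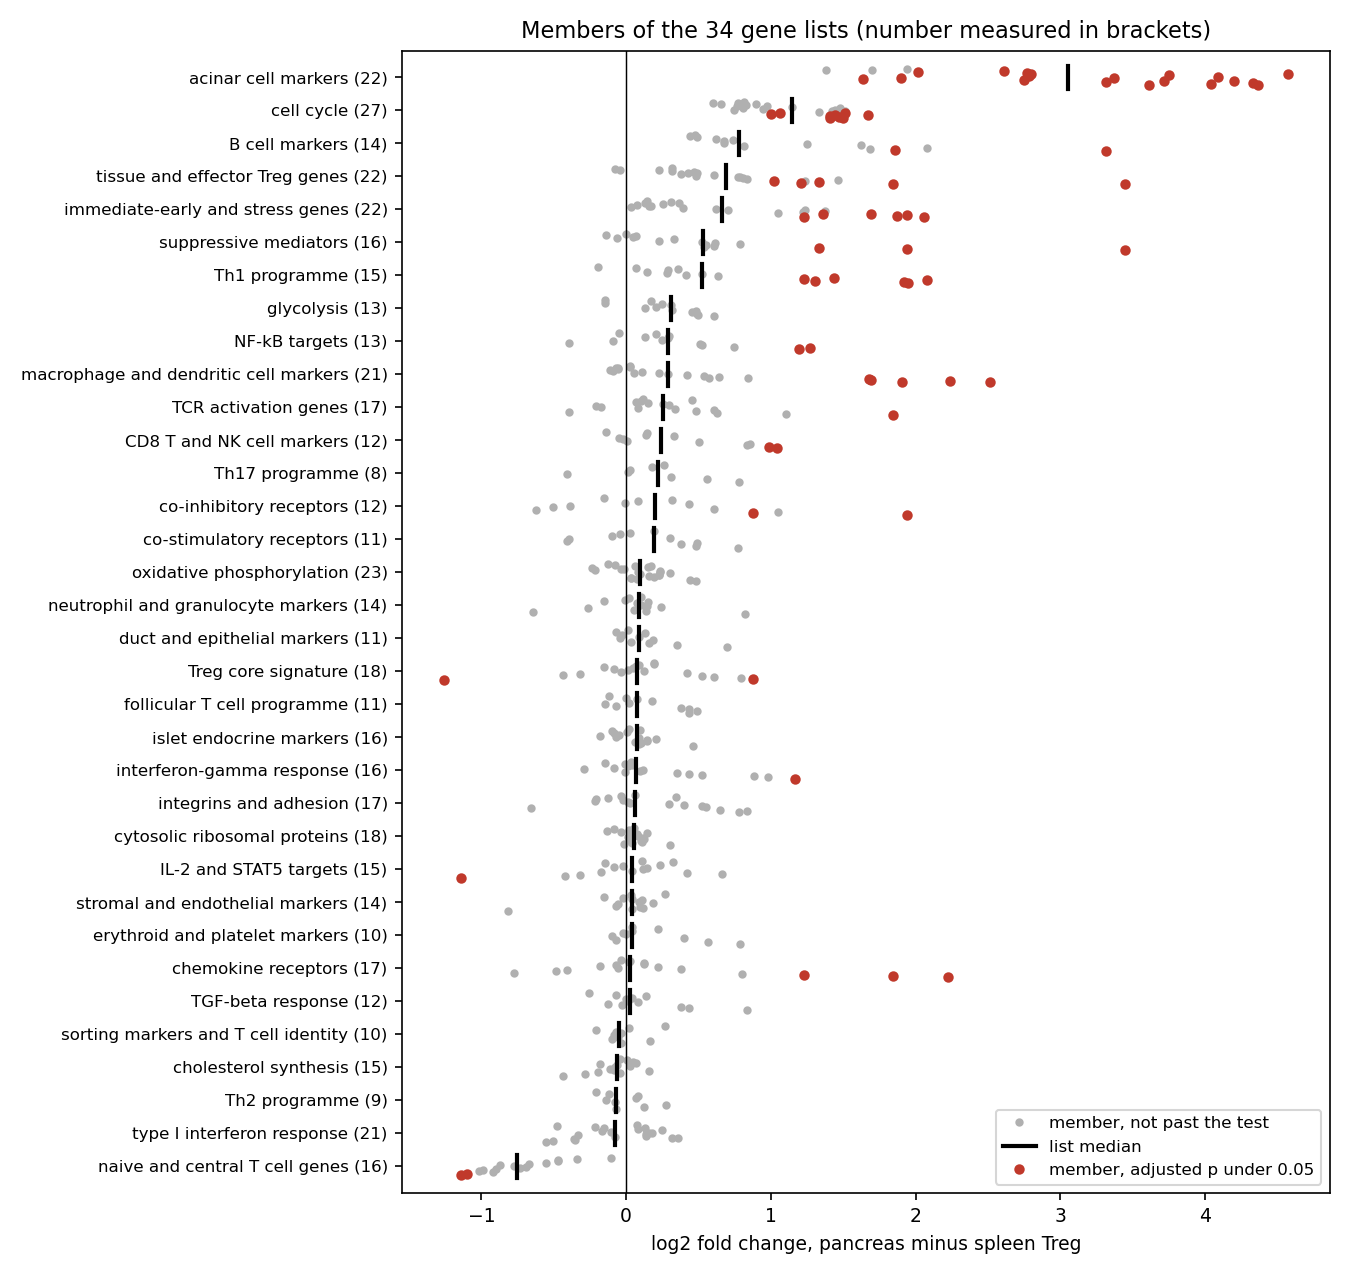
Log2 fold change between pancreatic and splenic Treg cells (horizontal axis, positive where higher in pancreas) of each measured member of the 34 gene lists (rows, number of members in brackets). Red points are members with an adjusted p under 0.05, grey points the others and black bars the list medians, which run from 3.05 for the acinar markers to -0.76 for the naive and central T cell genes.

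Markers of cells outside the sort gate were also higher on the pancreas arrays. Among probe sets that name 1 gene, the largest differences were those of digestive enzyme genes made by acinar cells, the exocrine cells of the pancreas. The chymotrypsinogen gene Ctrb1 was at 11.98 ± 0.54 in pancreas and 7.41 ± 1.64 in spleen (23.8-fold, adjusted p = 0.00952), the colipase gene Clps 20.6-fold higher (adjusted p = 9.26e-05) and the carboxypeptidase gene Cpa1 20.1-fold higher (adjusted p = 0.00134). All 22 measured acinar genes had a higher mean in pancreas, 19 rose over all genes and 22 over the list alone (median 3.05, camera adjusted p = 1.22e-72, and adjusted p = 0.0984 with an estimated correlation). Trypsin genes among them are close copies whose probe sets may share signal. Without spleen array 3 Ctrb1 was 45.8-fold and Cpa1 30.3-fold higher. The call of Ctrb1 ended without pancreas array 1 (adjusted p = 0.0619), with a trended and robust variance (adjusted p = 0.0523) and with each array centred on its median (adjusted p = 0.0743). The islet endocrine markers did not pass (16 genes, median 0.07, adjusted p = 0.321), and the insulin gene Ins2 was at 6.55 ± 0.19 against 6.34 ± 0.07. The duct and epithelial list (11 genes, adjusted p = 0.0640) and the stromal and endothelial list (14 genes, adjusted p = 0.872) did not pass either.

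Of 21 macrophage and dendritic cell markers, 5 rose over all genes and 9 over the list alone. The MHC class II gene H2-Aa was at 8.81 ± 0.71 against 6.30 ± 0.28 (adjusted p = 0.00506), its invariant chain gene Cd74 4.72-fold higher (adjusted p = 0.00586) and the lysozyme gene Lyz2 3.74-fold higher (adjusted p = 0.00134). The list had a median of 0.29 (adjusted p = 6.79e-12, and adjusted p = 0.0984 with an estimated correlation). MHC class II genes are also expressed by B cells. All 14 measured B cell markers had a higher mean in pancreas, of which 2 rose over all genes and 12 over the list alone (median 0.78, adjusted p = 5.26e-21, and adjusted p = 0.100 with an estimated correlation). Jchain, the immunoglobulin joining chain gene, was at least 4.82-fold higher, with all 3 spleen arrays below background (adjusted p = 0.000975), Cd79a at least 2.91-fold higher, with 1 of 3 spleen arrays above background (adjusted p = 0.0482), and Ms4a1, the gene of CD20, at least 2.89-fold higher without passing the test (adjusted p = 0.0678). The call of Cd79a ended in 4 of the 6 fits with 1 array left out. Of 12 CD8 T and NK cell markers, 2 passed over all genes and 4 over the list alone, Klrc1 and Klrd1 being the 2, both below background in both tissues and named after their values were seen. That list passed (median 0.24, adjusted p = 9.20e-06, and adjusted p = 0.107 with an estimated correlation), but restricted to members above background it did not, with a median of -0.02. The erythroid and platelet markers passed (10 genes, median 0.04, adjusted p = 0.0356, and adjusted p = 0.424 with an estimated correlation) with 0 genes past the test over all genes and 2 over the list alone, Ppbp being at 0.78 (adjusted p = 0.0842). That call ended in 3 of the 6 fits with 1 array left out (adjusted p up to 0.248, and a median of -0.0691 without pancreas array 3) and in 8 other settings, among them quantile normalization, array weights and both background settings. The neutrophil and granulocyte markers did not pass (14 genes, adjusted p = 0.466).

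**Figure D3:**
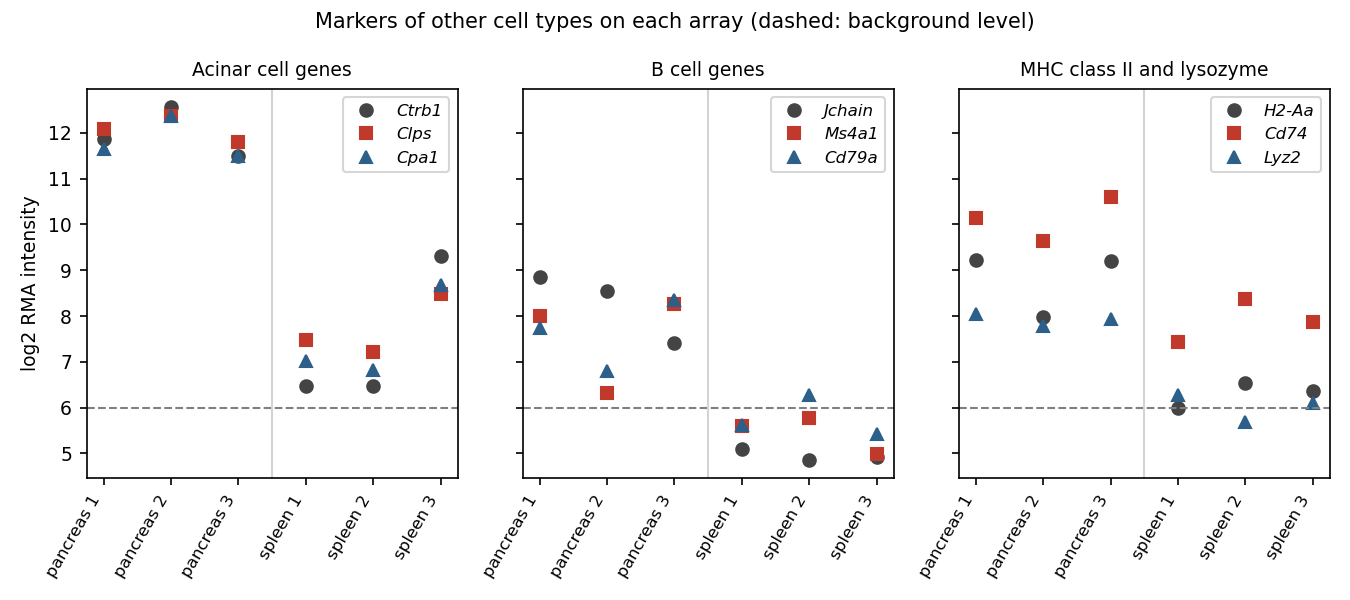
Log2 RMA intensity (vertical axis) on each of the 6 arrays (horizontal axis) for 3 acinar genes, 3 B cell genes, and 2 MHC class II pathway genes with lysozyme. Each symbol is 1 gene and the dashed line the background level (intensity 63.9, drawn on the log2 scale); Clps, at 12.09 ± 0.29 in pancreas and 7.72 ± 0.67 in spleen (mean ± SD, n = 3 each), was higher on all 3 pancreas arrays than on any spleen array.

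In all, 20 of the 34 lists passed camera with its preset correlation, 19 higher and 1 lower in pancreas, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.0984. In fry, which asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes, 8 lists passed: the tissue and effector Treg, naive and central T cell, Th1, immediate-early, cell cycle, acinar, macrophage and dendritic cell, and CD8 T and NK cell lists. Without pancreas array 1, camera passed 13 lists.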

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

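The probe sets that name no gene or several were left out of the gene comparison, and some of them carried signal that differed between the tissues. Of 3497 such probe sets, 10 passed the test when all probe sets were fitted together, 9 of them higher in pancreas and 1 higher in spleen. Of the 9, 5 name several genes and 4 name none. The largest log2 fold changes were 4.96 ± 0.75 SE (adjusted p = 0.0481) and 4.93 ± 0.77 SE (adjusted p = 0.0498), both from probe sets that name several genes, with an SD over the 3 spleen arrays of 1.80 and 1.85. Which transcripts these are is not analysed here, and no explanation was tested.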

How the results depend on the processing

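The alternatives on the spread of the arrays, and the 2-fold count without marker genes of other cells, were chosen after seeing the data. Of the 52 named genes past the test, 22 stayed past it whichever array was left out, and of the 20 lists 10 did. With arrays centred on their medians 22 of the 52 stayed past it: Il10, Pla2g1b, Ccl3, Lilr4b, Lilrb4a, Dmbt1, Cxcr6, Ccr8, Fos, Fosb, Rgs2, Gzmk, Nkg7, Ifng, Amigo2, Tlr7, Clps, Cpa1, Jchain, H2-Aa, Cd74 and Lyz2. With values floored at background 3 genes passed, in both counts, but flooring also took the calls of the 89 genes whose values it left unchanged. Unless named, the cause of a change was not tested. The count of 134 genes became 203 after repeated quantile normalization, 38 with arrays centred on their medians, 7206 with array weights, 76 over all probe sets, 46 at an adjusted p under 0.01, 77 without the marker genes of other cells, 538 with the spread as a covariate and 347 without the 2 arrays of narrowest spread. The array weights did not converge and put 9.50 on pancreas array 2 and 5.69 on spleen array 2 against at most 0.650 on the others, and with them 52.8% of the calls were higher in pancreas against 80.6% before. The count of 119 genes became 38 with centring, 215 with array weights, 31 at 4-fold, 69 without the marker genes and 194 without the 2 narrowest arrays. Leaving out 1 array gave 64 to 262 genes, 64 to 187 genes at least 2-fold apart and 13 to 23 lists. Of the 20 lists, 0 passed with an estimated correlation and 8 in directional fry.

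Arrays with the same number in their names had residual correlations of -0.46, 0.11 and -0.68 across genes. These cannot show whether arrays were paired, since the residuals also ran with the width of the arrays. The narrow pancreas array 3 and spleen array 1 correlated at 0.65, and the wide pancreas array 1 and spleen array 3 at 0.51. With the number as a replicate block, 132 genes passed, 102 of them shared with the 134, all 132 at least 2-fold apart, and 19 lists. The block ended the calls of Bcl2 (adjusted p = 0.0546), Zfp617 (0.0536) and Tigit (0.162).

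Reversed signs were all of lists or genes not past the test, except the co-inhibitory list (-0.16 without shared members) and the CD8 T and NK list (-0.0202 with members above background). A list reverses where the direction of its test turns, and its median need not. Th2 had medians of -0.0685 with the replicate block, the trended variance and fry, -0.0691 with array weights, -0.0394 with quantile normalization, -0.0426 with the spread covariate, -0.0856 with centring and 0.0445 without the narrowest arrays. The IL-2 and STAT5 list had 0.0430 in both dim-gene filters, 0.15 with array weights, 0.11 without shared members and 0.0955 with the spread covariate. The identity list had -0.0482 in both filters and 0.00311 with the spread covariate. The stromal list had 0.0174 above the median gene, 0.0898 above background, 0.0417 in fry and 0.0148 with the spread covariate. Others were cholesterol synthesis (0.0184, array weights), the core signature (0.0127) and co-stimulatory receptors (-0.0693) without shared members, type I interferon (-0.00453, spread covariate) and islet markers (-0.0242, narrowest arrays). Cd4 was at 0.16 with array weights and 0.0107 with the spread covariate, Ikzf2 at -0.0796 and Prf1 at 0.0672 with array weights, and Foxp3 at 0.00236 with the spread covariate. With 1 array left out, medians spanned -0.0576 to 0.0380 for Th2, -0.0358 to 0.10 for stromal, -0.14 to 0.0560 for type I interferon, -0.16 to 0.22 for IL-2 and STAT5, -0.15 to 0.0470 for cholesterol, -0.0766 to 0.20 for islet, -0.0666 to 0.19 for neutrophil, -0.16 to 0.0425 for identity, 0.0104 to 0.16 for core and -0.0397 to 0.17 for ribosomal genes, and values spanned -0.31 to 0.15 for Cd4 and -0.22 to 0.0718 for Foxp3.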

Other observations

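Of the 134 genes past the test, 69 stood on none of the fixed lists, 46 higher in pancreas and 23 higher in spleen. The genes named in this paragraph were chosen after their values were seen. Higher in pancreas were Il1r2, which encodes the decoy receptor of interleukin 1 (log2 fold change 1.91 ± 0.20 SE, adjusted p = 0.00173), and the metallothionein gene Mt2 (1.90 ± 0.20 SE, adjusted p = 0.00173). The transcription factor gene Bhlhe40 was 3.58-fold higher (adjusted p = 0.0473), the G protein regulator gene Rgs16 2.29-fold (adjusted p = 0.0354) and the semaphorin gene Sema7a 1.95-fold (adjusted p = 0.0245). The fatty acid binding protein gene Fabp5 was 1.96-fold higher (adjusted p = 0.0361), and Gatm, a creatine synthesis gene also expressed in the pancreas, at least 2.43-fold, with 2 of 3 spleen arrays above background (adjusted p = 0.0295). Genes of DNA replication and mitosis outside the fixed cell cycle list included Dtl (2.87-fold, adjusted p = 0.00363), Cdca8 (2.79-fold, adjusted p = 0.0157), Chek1 (at least 2.30-fold, with 1 of 3 spleen arrays above background, adjusted p = 0.0210) and Kif4 (at least 1.52-fold, with all 3 spleen arrays below background, adjusted p = 0.0256). No enrichment was tested for them.

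With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split called 134 genes and 119 at least 2-fold apart, and the highest of the other 9 splits called 0 in both counts, so 1 of 10 splits gave as many in each. For lists, 4 of the 10 splits passed at least 20 in camera, the highest of the others passing 21, so the number of lists past camera does not set the tissue split apart. Of the lists past camera, those of NF-kB, TCR activation, interferon gamma, glycolysis, oxidative phosphorylation, integrins and erythroid cells had a larger mean shift in another split. For NF-kB it was 0.375 against up to 0.503, and for oxidative phosphorylation 0.109 against up to 0.320. The other lists past camera had their largest mean shift in the real split. In directional fry, a comparison added after the results were seen, the real split passed 8 lists and the highest of the other 9 passed 2.

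The tests of explanations that follow were chosen after the results were seen, except the comparisons with random lists matched on mean expression. Random lists were drawn gene by gene, so their ranges do not allow for correlation within a list. Acinar genes were higher on the pancreas arrays although the gate required CD45, CD4, TCRb and GFP, which acinar cells lack. Different brightness or spread of the arrays does not account for it, since the list's median of 3.05 lay outside the range of random lists of the same size (-0.17 to 0.04). The excess over spleen arrays 1 and 2 ranked alike on the 3 pancreas arrays (lowest Spearman rho across the 22 genes 0.927), but so did that of the 80 called genes higher in pancreas on no list of other cells (0.908), so this order does not identify a source. Spleen array 3 had more of these transcripts than both other spleen arrays for 19 of 22 genes, and its excess also ranked like that of the pancreas arrays (rho = 0.949). Probe brightness and abundance can set that order too, and the share per gene ran from -2.82% to 13.1% of the pancreas excess (median 6.46%). Whether RNA of acinar cells, free or in sorted cells, is the source on either tissue's arrays stays open.

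Th1 genes were higher on the pancreas arrays, and the list's median of 0.527 lay outside the range of random lists (-0.18 to 0.08). A shift that different brightness or spread gives all genes of the same mean level therefore does not account for it. That range does not allow for the list's correlation, estimated at 0.30, with which camera gave adjusted p = 0.0984. CD8 T cells could carry Ccl5, Nkg7 and Gzmk. The mean log2 fold change of Cd8a and Cd8b1 had an upper 95% limit of 0.265, but both genes were above background on every array, between 7.25 and 7.88, so a small share would not show. NK cells stay open too, since Gzma reached at most 5.75, below background, on a pancreas array and Prf1 had an upper limit of 0.239, while the NK receptor genes Klrc1 and Klrd1 passed the test below background. Both cell types lie outside the gate, and a Th1-like state of the pancreatic Treg cells remains an open hypothesis that these tests do not settle.

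Immediate-early genes were higher on the pancreas arrays. The heat-shock genes Hspa1a, Dnajb1, Hsph1 and Hspa8 had a median log2 fold change of 0.212 and an SD of 0.533. Their median lay below the smallest of the AP-1 genes Fos, Fosb, Jun and Junb, 1.23, by more than that SD, although Hspa1a alone was at 1.22. The AP-1 genes were chosen after their values were seen, and the whole immediate-early list had a median of only 0.663. This comparison therefore cannot decide, and a heat-shock response during preparation as the whole cause stays open. The TCR activation list, with a median of 0.251 and an SD of 0.527, also lay below the smallest of these AP-1 genes. Within it Nr4a2 was at 1.85 and Nr4a1 at 1.10, while 3 of 17 genes had a lower mean in pancreas. For the same reason, acute TCR stimulation as the whole cause stays open too. Handling or digestion that differed between the tissues cannot be told apart from tissue, since each preparation holds 1 tissue. For 4 of the 4 genes Fos, Fosb, Jun and Junb every pancreas array lay above every spleen array. A difference between the tissues in the animal stays open and untested.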
